A study of Mus musculus with 7 samples.

How the data were processed

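RNA was measured by full-length cDNA sequencing (Smart-Seq2, a method that reverse-transcribes polyadenylated RNA from a few cells and amplifies the cDNA) in mouse oocytes taken from secondary follicles. Per the labels' protocols, follicles were freed from C57BL/6J ovaries with collagenase, oocytes were separated from granulosa cells with a second enzyme digestion, 5 oocytes went into each library, libraries were made with a transposase kit (Nextera XT) that does not mark strand, and 75-base paired reads were sequenced. The libraries fall into WT (n = 4) and KO (n = 3) by their titles. The labels disagree on other points. The series title and design text name Mfn2 as the deleted gene, while the genotype label and the treatment protocol name Mfn1. The protocol gives an age of 8 weeks, while the age label reads P1. The design text gives 3 mice per group, while 4 WT libraries are listed. All 7 libraries entered the tests in the groups their titles give. The labels do not say which mouse or mice each library came from, so p-values measure only the spread between these samples.

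The deposited table holds 1 normalised signal value per gene and library for 26019 gene rows, with chromosome, start, stop, strand and gene type. Per the submitters' processing notes, the tools were cutadapt, FastQC, STAR, DESeq and DESeq2, and the genome build was GRCm38 (mm10). The counter and its settings are not given in the sources used here. The values were gene counts divided by 1 size factor per library: within a library the low values were whole multiples of 1 step, and after division by that step 100% of the values of up to 1000 reads, and at least 99.9% of all values in each library, lay within 0.05 of a whole number. The size factors ranged from 0.914 to 1.10, and median-of-ratios factors computed from the recovered reads differed from them by at most 0.0082%. The recovered totals ranged from 6676076 to 8343915 reads per library, with 19518 to 20663 genes having at least 1 read. Gene rows were matched to GENCODE release M21, 23734 by name and start and 1227 more by position. Annotation ends and identifiers come from that release, and 1058 rows had no match. A spreadsheet had turned 24 gene symbols into dates, and 1 of these occurred on both of its rows. The table holds no rows of the mitochondrial chromosome, so mitochondrially encoded mRNAs were not analysed here.

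The test fixed before the data were examined was edgeR on counts, with limma as the stated replacement if the file held normalised values. Because it did, the main test was limma (version 3.58.1 in R 4.3.3) with an intensity trend and robust variance estimation on log2(value + 1), over the 19227 genes with a value of at least 1 in at least 3 libraries, with Benjamini-Hochberg adjusted p under 0.05. "Called" means past that threshold. A fold change on this scale understates the change of low genes. Fold changes are KO over WT, with the standard error (SE) of the fit. Means ± SD are of the normalised counts over 4 WT and 3 KO libraries. As an alternative added after seeing the data, edgeR (4.0.16) was run on the recovered reads. It called 1255 genes. DESeq2 (1.42.0) was an alternative chosen in advance. On simulated counts with 200 changed genes among 19227, built from the means and library sizes of the KO and WT comparison, limma called 58.0% of the genes changed by 1 log2 unit and 90.0% of those changed by 2, with 9 unchanged genes among its 157 calls. The changed genes were drawn only from genes above a minimum mean count. These shares thus do not hold for the genes with the lowest counts.

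The 34 gene lists were fixed before the data were examined, and 33 had at least 5 tested members. They were tested with camera from limma at a preset correlation of 0.01 between genes, on the log2 values (the fixed design named voom values of counts), with adjusted p over the 33 lists. Camera with an estimated correlation and fry were run beside it. In the simulation the list shifted by 0.5 log2 units was called, and 0 of 30 unchanged lists were. Its genes were drawn independently of each other, while in the real data the estimated correlation was 0.395 for cytosolic ribosomal proteins. The simulation thus does not show how often camera calls unchanged lists of correlated genes. Library composition was compared with 2-sided exact permutation tests over the 35 splits of 7 libraries into 4 and 3, whose smallest possible p is 0.0286. The genes named are Mfn1 and Mfn2, then the 12 called genes with the largest fold change in each direction whose KO and WT libraries did not overlap in CPM (reads scaled to a common library total) and whose higher group averaged at least 20 CPM, leaving out names of the Gm-number, Rik or ps type, then up to 4 members per list with the smallest p. Not every gene that this rule selected is given in the text, and 1 of those selected is not reported here. Genes that were chosen after their values were seen are said to be so. Reads shared between genes were estimated as the share of a gene's 75-base stretches that the longest transcript of another gene also holds. The kit does not mark strand, so reads of a gene and of its antisense or overlapping partner cannot be told apart.

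Replicate numbers occur in both groups, but nothing in the labels ties equal numbers to a shared animal or day. No pair of libraries of 1 group agreed within sampling noise: the chi-square per degree of freedom over genes was at least 5.44 for pairs of WT libraries and 17.6 for pairs of KO libraries, where counting noise alone gives about 1. Alternatives tried were edgeR with other scalings, DESeq2, limma voom with quality weights, other filters on low values, another pseudocount, other thresholds, a replicate block, detected genes as a covariate and each library left out in turn. Alternatives added after seeing the data were edgeR with TMM on recovered reads, values rescaled to equal totals, the granulosa marker mean as a covariate, KO 2 and KO 3 left out together, and removal of each library's trend with GC content and transcript length.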

Results

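Gene expression was measured in 7 libraries of 5 pooled mouse oocytes each, from secondary follicles, in which a growing oocyte is surrounded by layers of granulosa cells. The comparison is of wild type (WT, n = 4 libraries) with knockout (KO, n = 3 libraries), in a study on mitofusin 2. Mitofusin 2 is a GTPase of the outer mitochondrial membrane that fuses mitochondria and tethers them to the endoplasmic reticulum. WT libraries held 7741141, 6676076, 7231944 and 6883684 reads in genes, and KO libraries 7516486, 8343915 and 6851042. The size factors were near 1, so a normalised count is close to a number of reads per library. The first principal component, with 34.0% of the variance, had all 4 WT libraries on one side (-30.8 to -49.4) and the KO libraries on the other, with KO 1 nearer to WT (16.6) than KO 2 (73.6) and KO 3 (60.5). Pearson correlations across genes, which are not independent replicates, were 0.969 to 0.972 between WT libraries, 0.964 to 0.967 between KO libraries and 0.945 to 0.967 between the groups.

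The targeted gene was examined first. Mfn2 (ENSMUSG00000029020.13; GRCm38 chromosome 4, 147873599 to 147904704, minus strand) was lower in KO, at 28.7 ± 9.56 normalised counts (SD, n = 4) in WT and 6.49 ± 1.70 (SD, n = 3) in KO, a log2 fold change of -1.94 (SE 0.40; limma adjusted p = 0.00571). Its values were 35.3, 35.1, 15.0 and 29.2 in WT libraries and 7.27, 4.55 and 7.66 in KO libraries, so each KO library lay below each WT library. Mfn1, the paralog that the genotype label names (ENSMUSG00000027668.13; chromosome 3, 32529465 to 32579239, plus strand), had 289 ± 36.3 in WT and 330.3 ± 19.9 in KO (log2 fold change 0.20, SE 0.16; limma adjusted p = 0.499). The KO libraries thus had less RNA of the gene in the series title, and no difference past the threshold in the gene of the genotype label. The counts are per whole gene, and which exons were deleted is not given in the sources used here. The Mfn2 call was kept in each of the 7 fits that left out 1 library. It ended with KO 2 and KO 3 both left out (log2 fold change -1.77, adjusted p = 0.158) and with the granulosa marker mean as a covariate (-1.65, adjusted p = 0.427). Over all alternatives other than the leave-one-out fits, adjusted p ranged from 0.000462 to 0.427.

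**Figure D1:**
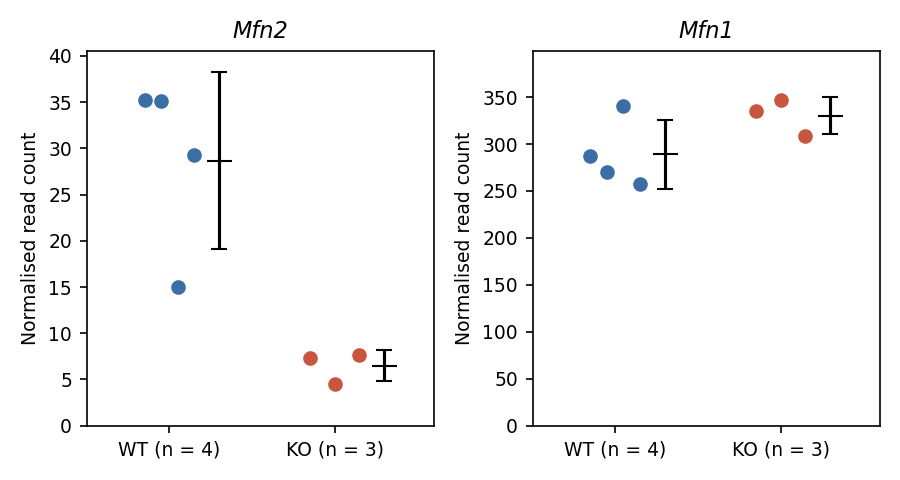
Normalised read counts of Mfn2 (left) and Mfn1 (right) in each library, one point per library, with the mean and SD of each group beside the points (WT n = 4, KO n = 3). Mfn2 lay between 15.0 and 35.3 in WT and between 4.55 and 7.66 in KO, while the Mfn1 ranges of both groups overlapped.

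Across the transcriptome, 1291 of 19227 tested genes (6.71%) were called between KO and WT by limma, 594 higher and 697 lower in KO. Genes called at least 2-fold higher numbered 249 and those called at least 2-fold lower 387. The genes with the largest increases that met the naming rule were Maged1, a MAGE-family gene (40.1 ± 12.5 in WT and 206 ± 157 in KO), and Myot, which encodes a sarcomere protein (87.9 ± 23.8 and 283 ± 128). They were followed by Simc1 (71.2 ± 9.73 and 214 ± 50.7), Zfp975, a zinc finger gene (52.2 ± 2.84 and 158 ± 52.8), and Cxadr, which encodes a cell adhesion receptor (58.1 ± 19.4 and 159.5 ± 45.0). Next came Abi2, an actin regulator (log2 fold change 1.40, SE 0.21), Eif1a, a translation initiation factor (1.39, SE 0.20), Zfp386 (1.37, SE 0.23) and Tmx2 (1.28, SE 0.21). The last of the 12 were Ddx4, the germ cell RNA helicase also called Vasa (1.26, SE 0.20), Ctsl, the lysosomal protease cathepsin L (1.25, SE 0.31), and Nedd4, a ubiquitin ligase (1.24, SE 0.19). Adjusted p for these 12 genes lay between 0.000324 for Simc1 and 0.0388 for Maged1. Ddx4 (chromosome 13, 112598333 to 112652475) was the most abundant of them, with 785 ± 165 in WT and 1904 ± 536 in KO. With libraries left out 1 at a time, Maged1 lost its call without WT 1 to 4 or KO 3 and Ctsl without WT 1 to 4, KO 2 or KO 3, with adjusted p of up to 0.114 and 0.114. Other genes share 24.2% of the 75-base stretches of Zfp975 and 23.2% of those of Tmx2, so their counts are less certain. The same holds for genes that overlap another counted gene, since the libraries carry no strand. Among them were Tmx2 (Med19) and, of genes named further on, Atp8a2 (Nupl1), Raet1d (Raet1e), Gabpa (Atp5j), Mterf3 (Ptdss1), Vdac2 (Comtd1), Psph (Cct6a), Gapdh (Iffo1), Tdrd9 (Rd3l), Kdm1b (Dek and Tpmt), Rnf2 (Trmt1l) and Dnmt3l (Aire). Overlaps with a row of the Gm-number or Rik type were found for Simc1, Nedd4, Phb2, Mrps30, Hsp90b1, Sptlc2, Ormdl1, Casp8, Nlrp9b, Cpeb2, Cnot1 and Esr2, among others. Some named genes, among them Cxadr and Eif1a, had no match in the annotation release. They were not checked for shared stretches or overlaps. KO 2 and KO 3 also held more RNA of many, but not all, granulosa cell markers than the other libraries. Inha, chosen here after its values were seen, was at 395 and 338 against 54.5 in KO 1 and a mean of 30.03 ± 24.9 in WT.

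The largest decreases that met the rule were those of Cmtm8 (227 ± 50.7 in WT and 51.7 ± 34.0 in KO), Atp8a2, a phospholipid flippase (457 ± 105 and 97.3 ± 9.05), and Rgn, the calcium-binding protein regucalcin (557 ± 134 and 133 ± 53.1). Next were Popdc2, a membrane protein that binds cyclic AMP (171 ± 19.3 and 43.0 ± 16.7) and Slc9b1, a member of the sodium/proton exchanger family (434 ± 99.5 and 121 ± 73.5). Atp8a2 (ENSMUSG00000021983.16; chromosome 14, 59638540 to 60197179, minus strand) had the smallest p of the named genes, with a 4.58-fold lower level in KO (log2 fold change -2.19, SE 0.19; limma adjusted p = 2.62e-06). The others were Tnip3 (-1.82, SE 0.36), Raet1d, a ligand of a natural killer cell receptor (-1.80, SE 0.24), Vmn1r139, of the vomeronasal receptor family (-1.70, SE 0.26), and Ms4a1, the gene of the B cell surface protein CD20 (-1.60, SE 0.33). Pdzph1 (-1.55, SE 0.21), Daw1, a dynein assembly gene (-1.55, SE 0.22), and Epp13 (-1.52, SE 0.28) completed the 12. Other genes hold 100% of the 75-base stretches of Vmn1r139 and 29.0% of those of Raet1d, so their counts are uncertain. Cmtm8 lost its call without KO 3 (adjusted p = 0.103), and Slc9b1 without WT 1 or KO 3 (up to 0.135). Ms4a1 lost its call without WT 1, WT 3 or KO 3 (up to 0.119).

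The number of called genes depended on single libraries. In place of 1291 calls, limma gave 728 without WT 1, 710 without WT 2 and 594 without WT 3. It gave 604 without KO 2 and 821 without KO 3. It called 98 genes, of which 1 was higher, without both KO 2 and KO 3, which leaves a lone KO library assumed to vary like WT. With the granulosa marker mean of each library as a covariate it called 11 genes, 0 of them higher, among 1635 genes at an unadjusted p under 0.05.

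**Figure D2:**
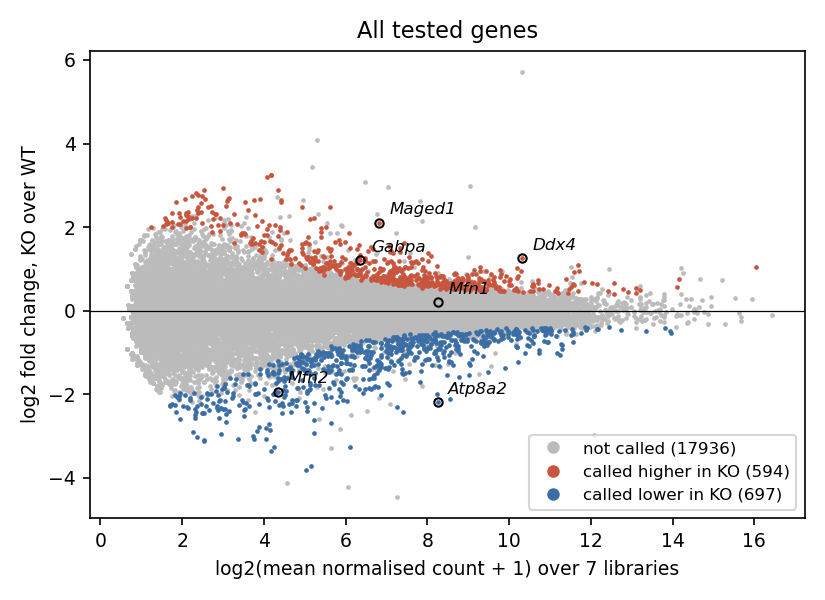
Log2 fold change of KO over WT (vertical axis) against log2 of the mean normalised count plus 1 over the 7 libraries (horizontal axis), one point per tested gene. Red points are the 594 genes called higher in KO, blue points the 697 called lower, grey points were not called, and 6 genes of the text are circled and named.

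**Figure D3:**
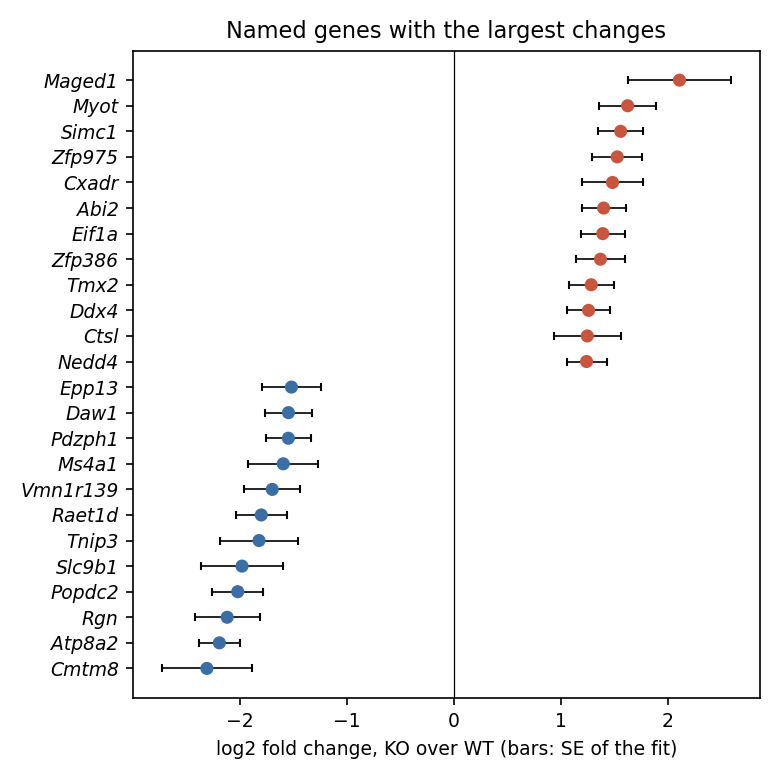
Log2 fold changes of KO over WT for the 12 genes with the largest increase (red) and the 12 with the largest decrease (blue) under the naming rule. Horizontal bars show the standard error of the fit, and values run from -2.31 for Cmtm8 to 2.11 for Maged1.

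Lists of mitochondrial genes, which the study's subject puts first, had few called members. Among 30 genes of mitochondrial fusion, fission and cristae, Mfn2 itself and Phb2, a prohibitin of the inner membrane, were called lower (Phb2 log2 fold change -0.48, SE 0.14; limma adjusted p = 0.0418), and 0 were called higher. In this list 3 rose and 3 fell when adjusted over the list alone. The set was not called (camera adjusted p = 0.527). Of 77 nuclear-encoded subunits of the respiratory chain and ATP synthase, Atp5g3, a subunit of the proton ring, was called higher (396 ± 20.48 and 795 ± 161; adjusted p = 0.000814). Ndufa8 of complex I was called lower (1954 ± 121 and 1477 ± 63.4; adjusted p = 0.0475), and 75 did not pass (1 rose when adjusted over the list alone). The respiratory chain set had a camera adjusted p of 0.798. It was called higher without KO 1 (0.0333) and lower with the granulosa marker mean as a covariate (0.000365). Of 22 genes of mtDNA maintenance and mitochondrial biogenesis, 2 rose and 0 fell, and 3 rose when adjusted over the list alone. The called genes were Gabpa, a transcription factor of mitochondrial genes (51.4 ± 7.47 and 121 ± 27.4; adjusted p = 0.00326), and Mterf3 (727 ± 67.1 and 1026 ± 143; adjusted p = 0.0379). Tfam, which packages mitochondrial DNA, had 322 ± 27.6 and 439 ± 8.46 but did not pass over all genes (adjusted p = 0.0684).

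The mtDNA maintenance list was called higher as a set (camera adjusted p = 0.0383; adjusted p = 0.536 with an estimated correlation). The call was lost without WT 1 (adjusted p = 0.0559), WT 3 (0.101) or KO 2 (0.0933). Over the other alternatives its adjusted p ranged from 0.0304 to 0.165. Of 78 mitochondrial ribosomal proteins 1, Mrps30, fell (list adjusted p = 0.219; 0 when adjusted over the list alone). Of 21 mitochondrial chaperones and proteases 1, the import receptor Tomm20, rose (list adjusted p = 0.163; 3 when adjusted over the list alone). Leaving out 1 library at a time ended the call of Phb2 without WT 1, WT 2, WT 3, KO 2 or KO 3 (adjusted p up to 0.148), of Ndufa8 without WT 1 to 4, KO 1 or KO 2 (0.111) and of Mterf3 without WT 1 to 4, KO 2 or KO 3 (0.122). It also ended the call of Mrps30 without WT 1, WT 2, WT 3, KO 2 or KO 3 (0.152) and of Tomm20 without WT 2, WT 3, KO 2 or KO 3 (0.0988).

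Genes at the contact of mitochondria with the endoplasmic reticulum and of calcium handling included 2 of 29 that fell and 0 that rose (1 rose and 3 fell when adjusted over the list alone). Vdac2, a channel of the outer mitochondrial membrane, had 2136 ± 164 in WT and 1108 ± 82.8 in KO (log2 fold change -0.95, SE 0.12; limma adjusted p = 0.000243). Mcu, the pore of the mitochondrial calcium uniporter, had 312 ± 38.3 and 161 ± 39.4 (-0.97, SE 0.18; adjusted p = 0.00318). The list as a set was not called (adjusted p = 0.527). Of 38 mitophagy and autophagy genes 2 rose, the lysosomal membrane gene Lamp2 (84.8 ± 13.9 and 168 ± 12.8; adjusted p = 0.00513) and the kinase gene Tbk1 (145 ± 24.8 and 229.9 ± 51.4; adjusted p = 0.0485). The call of Tbk1 was lost without WT 1 to 4, KO 2 or KO 3 (up to 0.182). When adjusted over the list alone 4 rose. The set was called higher (camera adjusted p = 0.0433; adjusted p = 0.536 with an estimated correlation). The call was lost without WT 1 (0.0513), WT 3 (0.104), WT 4 (0.0825) or KO 2 (0.283). Across the other alternatives its adjusted p ranged from 0.0304 to 0.165. Among 25 chaperones and unfolded protein response genes of the endoplasmic reticulum 1 rose, Hsp90b1 (1641 ± 269 and 2536 ± 615; adjusted p = 0.0337, lost without WT 2, WT 3, KO 2 or KO 3, up to 0.148). There were 5 higher and 1 lower when adjusted over the list alone (list adjusted p = 0.731). Of 30 targets of ATF4 in the integrated stress response 1 rose, Psph of serine synthesis (60.8 ± 10.02 and 125 ± 14.5; adjusted p = 0.00654), with 1 when adjusted over the list alone (list adjusted p = 0.664).

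Ceramide and sphingolipid metabolism had called members in both directions. Of 33 genes 3 rose and 2 fell (5 and 2 when adjusted over the list alone; list adjusted p = 0.250). Asah1, the lysosomal acid ceramidase, was 3.63-fold higher (31.4 ± 8.63 and 115 ± 22.2; limma adjusted p = 0.000482). Ormdl1, a regulator of serine palmitoyltransferase, had 799 ± 85.5 and 1349.5 ± 203 (adjusted p = 0.00288). The serine palmitoyltransferase subunit genes Sptlc2 (708 ± 63.03 and 361 ± 43.6; adjusted p = 0.000573) and Sptssb (141 ± 40.7 and 44.9 ± 11.8; adjusted p = 0.000713) fell. A further small subunit gene, Sptssa, named after its values were seen, rose (322 ± 42.1 and 536 ± 64.5; adjusted p = 0.00710). Of 39 apoptosis and p53 or p63 target genes 2 rose, Casp6 (53.3 ± 7.51 and 109 ± 27.4) and Birc2 (74.1 ± 11.7 and 134 ± 40.1). In the same list 2 fell, Bik (101.1 ± 13.4 and 52.4 ± 18.5) and Casp8 (665 ± 70.3 and 463 ± 50.8), with 2 and 2 when adjusted over the list alone (list adjusted p = 0.463). Casp6 lost its call without KO 2 (adjusted p = 0.0871) and Birc2 without WT 2, WT 3, WT 4, KO 2 or KO 3 (up to 0.156). Bik lost it without WT 2, WT 3, WT 4, KO 2 or KO 3 (0.0994) and Casp8 without WT 1, WT 2, WT 3, KO 1 or KO 2 (0.114).

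Of 32 antioxidant genes 3 rose and 0 fell (4 and 0 when adjusted over the list alone). Gpx1, a glutathione peroxidase, had 645 ± 37.4 and 1170.4 ± 368 (limma adjusted p = 0.00495). Gsr (31.9 ± 5.39 and 70.03 ± 29.4) lost its call without WT 1 to 4, KO 1 or KO 2 and Gpx8 (0.780 ± 1.03 and 6.55 ± 3.33) without WT 1, WT 2, WT 3, KO 2 or KO 3 (adjusted p up to 0.218 and 0.166). The antioxidant set was called higher (camera adjusted p = 0.0433; adjusted p = 0.567 with an estimated correlation). The call was lost without WT 2 (0.0712), WT 3 (0.113), KO 2 (0.321) or KO 3 (0.0620). In the other alternatives its adjusted p ranged from 0.0378 to 0.965. Of 27 telomere maintenance genes 0 were called by limma and 0 by edgeR, with 2 at an unadjusted p under 0.05 (list adjusted p = 0.856; 0 when adjusted over the list alone).

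In energy metabolism and growth signalling, 2 of 29 genes of glycolysis and pyruvate metabolism rose, Gapdh (195 ± 45.1 and 351 ± 135; limma adjusted p = 0.0493) and Ldha (1.25 ± 1.19 and 15.8 ± 12.9; adjusted p = 0.0426). These calls were lost without WT 1 to 4, KO 2 or KO 3 (up to 0.194) and without WT 2, WT 3, WT 4, KO 2 or KO 3 (up to 0.198). When adjusted over the list alone 2 rose (list adjusted p = 0.124, and 0.0246 without KO 3). Other genes share 22.8% of the 75-base stretches of Gapdh. Of 25 genes of the tricarboxylic acid cycle 0 were called by limma and 1, Idh1, by edgeR, with 4 at an unadjusted p under 0.05 (list adjusted p = 0.277; 0 when adjusted over the list alone). Of 25 fatty acid oxidation genes 1 rose, Acsl4 (65.3 ± 17.3 and 119.6 ± 31.4; adjusted p = 0.0389, lost without WT 1, WT 2, WT 3, KO 2 or KO 3, up to 0.154). Of these genes 0 rose when adjusted over the list alone. That set was called higher (camera adjusted p = 0.0352; adjusted p = 0.536 with an estimated correlation). It was not called without WT 3 (0.104) or KO 2 (0.222). Over the other alternatives its adjusted p ranged from 0.0165 to 0.480. Of 35 genes of PI3K, mTOR and FOXO signalling 3 rose and 0 fell (4 and 0 when adjusted over the list alone; list adjusted p = 0.219). Among those that rose, Eif4ebp1, a translation repressor, had 79.5 ± 3.30 and 153 ± 32.4 (adjusted p = 0.00936, and 0.0676 without KO 2). Mlst8, a subunit of mTOR complexes, had 31.9 ± 1.61 and 58.5 ± 6.79 (adjusted p = 0.0491), a call lost without WT 1 to 4, KO 1, KO 2 or KO 3 (up to 0.171).

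In the list of small RNA and retrotransposon control, 4 of 23 genes rose and 1 fell (4 and 2 when adjusted over the list alone). Those that rose were Ddx4, Piwil2, a PIWI protein gene (45.0 ± 7.98 and 100.3 ± 12.05; limma adjusted p = 0.00567), Tdrd9, a helicase gene of the same pathway (105 ± 17.1 and 199 ± 23.4; adjusted p = 0.00719), and Tdrd5. The last was named after its values were seen (1009.5 ± 57.7 and 1406 ± 73.2; adjusted p = 0.0254, lost without WT 1 to 4 or KO 2, up to 0.0925). Henmt1, which methylates piRNA ends, fell (1443 ± 199 and 789.8 ± 158; adjusted p = 0.00147). The list as a set was not called (camera adjusted p = 0.0779). Of 20 genes of meiotic prophase and cohesin 2 rose and 0 fell (4 and 0 when adjusted over the list alone; list adjusted p = 0.138, and 0.0428 without KO 1). Smc1b, a meiotic cohesin, had 161 ± 21.3 and 342 ± 99.6 (adjusted p = 0.00348). Sycp2, of the synaptonemal complex, had 529 ± 29.4 and 788 ± 150.3 (adjusted p = 0.0283, lost without WT 1, WT 2, WT 3, KO 2 or KO 3, up to 0.0975).

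Of 47 maternal effect genes 6 rose and 1 fell (10 and 3 when adjusted over the list alone; list adjusted p = 0.174, and 0.0488 without KO 1). Besides Ddx4, Nlrp9b rose (4825 ± 485 and 7767 ± 2257; limma adjusted p = 0.0160, and 0.0609 without WT 3). Nlrp4f (5906 ± 531 and 8546 ± 1726) and the mRNA decay factor Zfp36l2 (50.1 ± 2.24 and 92.6 ± 9.76) rose too, both lost without WT 1, WT 2, WT 3, KO 2 or KO 3 (up to 0.0895 and 0.0746). Of those named after their values were seen, Nlrp14 (46346 ± 9110.5 and 96316 ± 26438) and Dazl, a germ cell RNA-binding protein gene (5313 ± 334 and 7036 ± 722), rose. Nlrp14 lost its call without WT 1, WT 2, KO 2 or KO 3 (up to 0.171) and Dazl without WT 1 to 4, KO 2 or KO 3 (up to 0.117). Khdc3, named likewise (11939 ± 1262 and 8556 ± 1399), fell (lost without WT 2, WT 4 or KO 3, up to 0.1002). No member of the zona pellucida and oocyte-secreted factors (16 genes; list adjusted p = 0.992) or of the oocyte transcription factors (18 genes; 0.664) was called by limma, 0 were when adjusted over the list alone, and 3 and 8 had an unadjusted p under 0.05. By edgeR 1 of each was called, Fgf8 and Figla. Zp2, which encodes a zona protein, had 29215 ± 6973 and 49401 ± 17918 (adjusted p = 0.229).

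Among regulators of RNA, chromatin and the cell cycle, calls went both ways. Of 33 genes of mRNA storage and decay 3 rose and 0 fell (5 and 2 when adjusted over the list alone; list adjusted p = 0.933). Cpeb2, a regulator of translation, had 9.12 ± 3.69 and 32.9 ± 8.52 (limma adjusted p = 0.00888, and 0.0513 without KO 3). Zfp36l2 rose as given above, and Cnot1, a scaffold of mRNA deadenylation, had 330.5 ± 43.7 and 493 ± 114 (adjusted p = 0.0491, lost without WT 1 to 4, KO 2 or KO 3, up to 0.195). Of 39 genes of DNA methylation and histone modification 3 rose and 1 fell (3 and 1 when adjusted over the list alone; list adjusted p = 0.299). Kdm1b, a histone demethylase needed for imprints in oocytes, had 1325 ± 172 and 2114 ± 429.7 (adjusted p = 0.0108, and 0.0636 without KO 2). Rnf2, of Polycomb complexes, had 735 ± 134 and 1044 ± 52.7 (adjusted p = 0.0341, lost without WT 1, WT 2, WT 3 or KO 2, up to 0.110). Kmt2a, a histone methyltransferase, had 1.75 ± 0.458 and 12.6 ± 8.07 (adjusted p = 0.0392, lost without WT 1 to 4, KO 1 or KO 2, up to 0.180). Dnmt3l, a cofactor of DNA methylation, had 655 ± 87.4 and 381 ± 145 (adjusted p = 0.0173, lost without WT 4, KO 2 or KO 3, up to 0.0929). Of 38 genes of the cell cycle and meiotic resumption Kif11 (296 ± 25.1 and 426 ± 60.2) rose and Ccnb2 (2066 ± 90.6 and 1563 ± 106) fell (0 when adjusted over the list alone; list adjusted p = 0.250). Both calls were lost without WT 1 to 4, KO 2 or KO 3 (up to 0.145 and 0.128). Of 40 genes of DNA damage response and repair 1, H2afx (1164 ± 98.0 and 805 ± 218), fell (0 when adjusted over the list alone; list adjusted p = 0.399). That call was lost without WT 1 to 4 or KO 3 (up to 0.160). Of 28 gap junction, transzonal and adhesion genes Gjc1 rose (7.11 ± 3.61 and 29.0 ± 4.01; adjusted p = 0.0103). Spire1, an actin nucleator, fell (941 ± 111 and 588 ± 75.7; adjusted p = 0.00684), with 4 and 2 when adjusted over the list alone (list adjusted p = 0.417). Of 82 cytosolic ribosomal protein genes 0 were called by limma and 0 by edgeR, with 7 at an unadjusted p under 0.05 (list adjusted p = 0.755; 0 when adjusted over the list alone). By camera that list was called higher without KO 1 (adjusted p = 0.0335) and lower with the granulosa marker mean as a covariate (0.00244).

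Heat shock and immediate early genes, listed as signs of how cells and RNA were handled, included members that rose with genotype. Of 27 members 5 rose and 0 fell (5 and 0 when adjusted over the list alone). These were Hsp90aa1 (14530 ± 1072 in WT and 21790 ± 3833 in KO; limma adjusted p = 0.00719), and Hspb1 (62.3 ± 17.6 and 138 ± 33.2; adjusted p = 0.00756). Others were Hsp90ab1 (2173 ± 280.3 and 4227 ± 1351; adjusted p = 0.0105, and 0.0993 without KO 3) and Ier2 (49.5 ± 16.1 and 102 ± 13.0; adjusted p = 0.0153, lost without WT 3 or KO 2, up to 0.0627). The last was Hsph1, named after its values were seen (1522 ± 162 and 2199 ± 284; adjusted p = 0.0204, lost without WT 1, WT 2, WT 3, KO 2 or KO 3, up to 0.0873). The set was called higher (camera adjusted p = 0.0334; adjusted p = 0.536 with an estimated correlation). The call was lost without WT 3 (0.101) or KO 2 (0.0544). Across the other alternatives its adjusted p ranged from 0.0136 to 0.0465. Other genes share 53.1% of the 75-base stretches of Hsp90aa1 and 47.3% of those of Hspb1, so these counts are less certain.

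Camera called 7 of 33 lists at the preset correlation, 6 higher and 1 lower, and 0 with estimated correlations, where 2 had an unadjusted p under 0.05. Fry, which tests whether the members of a list move on balance one way, gave 4 lists an adjusted p under 0.05. These were mtDNA maintenance (0.0434), PI3K, mTOR and FOXO signalling (0.0244), small RNA control (0.0244) and heat shock genes (0.0434). The median and mean log2 fold change differed in sign in 6 lists. They were -0.09 and 0.03 for ATF4 targets and -0.17 and 0.04 for the unfolded protein response, which camera placed lower. Among lists that camera placed higher they were -0.02 and 0.02 for the respiratory chain, -0.02 and 0.01 for cytosolic ribosomal proteins, -0.03 and 0.01 for zona and oocyte-secreted factors and -0.01 and 0.08 for mRNA storage.

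Markers of other ovarian cells differed between libraries. As a set, 24 tested granulosa cell markers were called higher in KO (median log2 fold change 1.13; camera adjusted p = 0.0113; adjusted p = 0.536 with an estimated correlation). It was not called without KO 2 (0.0933) or KO 3 (0.106). In the other alternatives its adjusted p ranged from 0.000226 to 0.904. Over all genes 0 members were called higher by limma and 0 by edgeR (6 were by limma when adjusted over the list alone, and 11 were higher at an unadjusted p under 0.05). Hsd17b1, Gja1 and Bex4 were called higher in some other fits, also with a library left out. Over the alternatives other than the leave-one-out fits, their lowest adjusted p was 0.0111, 0.0234 and 0.0206. Other genes share 38.3% of the 75-base stretches of Bex4. Cyp19a1, the aromatase gene (179 ± 28.4 and 78.2 ± 25.1; adjusted p = 0.00251), and Esr2, an estrogen receptor gene (1013 ± 106 and 722 ± 129; adjusted p = 0.0446, lost without WT 1 to 4, KO 1 or KO 2, up to 0.205), fell. The higher levels lay in 2 libraries: Inha, an inhibin subunit gene, had 395 in KO 2 and 338 in KO 3, but 54.5 in KO 1 and 11.9 to 66.7 in WT. The list took 0.0848% of reads in KO 2, 0.0812% in KO 3, 0.0695% in KO 1 and 0.0632 to 0.0748% in WT. Serpine2 held most of these reads (4275 normalised counts in KO 2, 3683 in KO 3 and 3740 in WT 4). The share thus largely follows that 1 gene. Of 16 markers with a WT mean under 10, 12 were higher in both KO 2 and KO 3 than in every WT library. Some listed markers did not rise there. Fshr had 9.09 in KO 2 and 6.56 in KO 3 against a WT mean of 14.2. Gata4 had 23.6 and 24.1 against 35.6. The genes called higher were measured in a group where 2 of 3 libraries also held more RNA of many, but not all, granulosa markers.

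**Figure D4:**
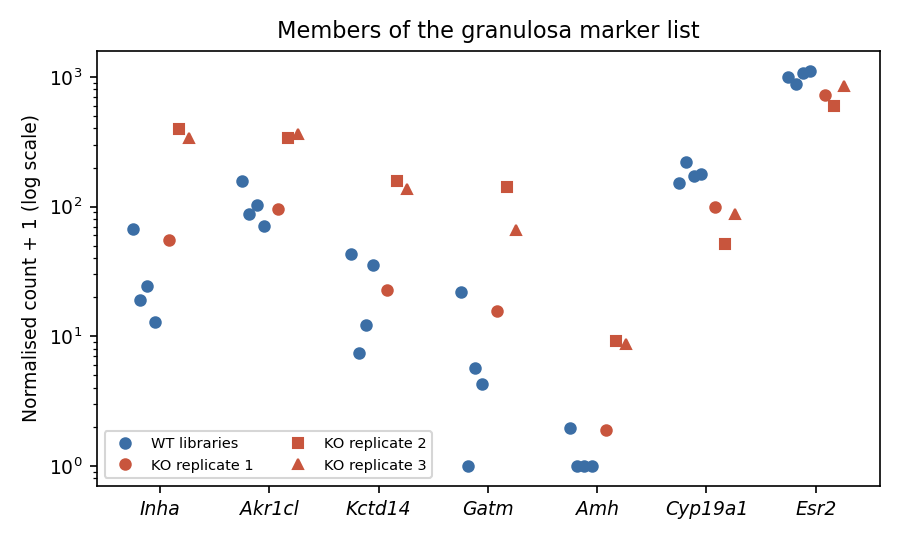
Normalised counts plus 1 on a log scale for 7 members of the granulosa marker list, 5 of them chosen after their values were seen, one symbol per library (blue circles WT, red symbols KO). Inha, Akr1cl, Kctd14, Gatm and Amh were higher in KO 2 and KO 3 than in KO 1 and the WT libraries, while Cyp19a1 and Esr2 were lower in all 3 KO libraries than in the WT libraries.

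Markers of blood, endothelial and immune cells were called lower as a set of 8 (median log2 fold change -0.82; camera adjusted p = 0.0433; adjusted p = 0.536 with an estimated correlation). The call was lost without WT 1 (0.0513), WT 3 (0.101), WT 4 (0.0825), KO 2 (0.0933) or KO 3 (0.113). Over the other alternatives that could test it, its adjusted p ranged from 0.0455 to 0.374. The 1 member that fell, also when adjusted over the list alone, was C1qb, a complement subunit gene, with 533 ± 17.1 in WT and 217 ± 39.1 in KO (log2 fold change -1.31, SE 0.16; limma adjusted p = 0.000124). Of 13 theca and stromal markers 0 were called by limma and 0 by edgeR, with 5 at an unadjusted p under 0.05 (list adjusted p = 0.722, with 0 when adjusted over the list alone). Among them, 8 had a positive and 5 a negative log2 fold change. Hsd3b1 of this list had 195 normalised counts in KO 2 and 327 in KO 3, against 23.6 in KO 1 and a mean of 17.4 in WT. It was called higher only in some of the other fits. Of 7 markers of the ovarian surface epithelium Krt8 rose (17.5 ± 9.31 and 50.8 ± 13.0; adjusted p = 0.0251, lost without WT 2, WT 3, KO 1, KO 2 or KO 3, up to 0.0720), also when adjusted over the list alone (list adjusted p = 0.547). By 2-sided exact permutation tests over 7 measures of composition, no difference passed for total reads (exact p = 0.400), genes with a read (0.83) or the share of reads in the 100 most abundant genes (25.3 ± 1.18% and 26.8 ± 1.78%; 0.200). The same held for the shares of granulosa (0.0857), theca and stromal (0.371) and surface epithelium markers (0.257). The share of blood, endothelial and immune markers was lower in each KO library than in each WT library (0.0112 ± 0.000581% and 0.00619 ± 0.00143%; exact p = 0.0286, the smallest that 35 splits allow), with a Benjamini-Hochberg adjusted p of 0.200 over the 7 measures. C1qb, at the 533 and 217 normalised counts given above, held most of the WT reads of this list, so the share largely follows that 1 gene.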

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

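No test in this part was chosen after the result was seen. Among the WT values of each named gene and each composition measure, a library was set apart where its gap to the nearest of the other 3, divided by the range of the 4 WT values, was above Dixon's 95% critical value. This held in 7 of 158 WT groups, and chance sets apart about 1 in 20. Cxadr had 29.2 normalised counts in WT 4 and 64.5 to 69.6 in the other WT libraries. Mtfr2, a gene of mitochondrial fission, had 1497 in WT 4 and 1199 to 1237 in the others. Bik had 81.0 in WT 1 and 107 to 109 in the others. Mlst8 had 29.6 in WT 1 and 32.5 to 33.0 in the others. Gja1, the main gap junction gene of granulosa cells, had 6.54 in WT 3 and 0 to 1.07 in the others. Rnf2 had 934 in WT 4 and 655 to 692 in the others. Hsd3b1, a gene of steroid synthesis, had 44.8 in WT 1 and 6.54 to 9.59 in the others.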

How the results depend on the processing

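The fits without both KO 2 and KO 3, with the granulosa marker mean as a covariate, on values rescaled to equal totals, with edgeR and TMM on recovered reads, and with the trend with GC content and transcript length removed were chosen after seeing the data. The direction of Mfn2 was kept in each alternative run for it (not run for single genes were detected genes as a covariate, other thresholds and the trend with GC content and length), and its call in all but 2, with log2 fold changes of -1.65 with the granulosa covariate and -1.77 without KO 2 and KO 3 (adjusted p = 0.427 and 0.158). Mfn1 stayed uncalled in the same alternatives. Of 1291 called genes, the count became 2184 at an adjusted p under 0.1, 636 with a log2 fold change of at least 1 as a further condition, 98 without KO 2 and KO 3 and 11 with the covariate, and it ranged from 594 (without WT 3) to 1767 (without KO 1) over the leave-one-out fits. In the other 12 alternatives it stayed within 1.5 times, where no filter and a filter of 1 read in all count as 1, since they kept the same 26019 genes. The last 2 settings leave 1 KO library, or use a covariate that follows KO 2 and KO 3, so fewer calls follow in part from how they are built.

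The 7 called lists became 1 (heat shock) with edgeR under median-of-ratios, total-count or TMM scaling, with the stricter filter of 20 reads and with voom and quality weights, 4 with equal totals and 4 without KO 2 and KO 3, and they ranged from 0 (without KO 2) to 11 (without KO 1). For the lists below the direction turned, and the cause was not tested. Without KO 2 and KO 3, adjusted p was 1.57e-05 for the respiratory chain, 0.000115 for cytosolic ribosomal proteins, both lower and called, 0.678 for telomere maintenance, 0.912 for zona factors and 0.914 for fusion and fission, for endoplasmic reticulum contacts and for oocyte transcription factors. With the granulosa covariate it was 0.000365 for the respiratory chain and 0.00244 for cytosolic ribosomal proteins, both lower and called, 0.835 for ATF4 targets and telomere maintenance, 0.965 for antioxidant genes, 0.861 for the tricarboxylic acid cycle and 0.714 for zona factors. The granulosa list turned there by construction, since its own mean is the covariate, so that fit does not test it. With equal totals it was 0.941 for the respiratory chain and zona factors and 0.998 for mRNA storage. With voom it was 0.613 for the respiratory chain, 0.659 for cytosolic ribosomal proteins, 0.966 for telomere maintenance and 0.911 for mRNA storage. With the stricter filter it was 0.983 for zona factors and 0.920 for mRNA storage, and with the replicate block 0.979 for the unfolded protein response. Over the leave-one-out fits the lists that turned in at least 1 ranged from 0.0333 to 0.974 (respiratory chain), 0.0335 to 0.996 (cytosolic ribosomal proteins), 0.320 to 0.988 (unfolded protein response), 0.558 to 0.996 (telomere maintenance), 0.561 to 0.971 (zona factors) and 0.822 to 0.988 (mRNA storage). Mitochondrial ribosomal proteins were called lower with the covariate (0.0195) and without KO 2 and KO 3 (0.000645), and small RNA control higher with no filter (0.0493).

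Among named genes that were not called, Zfp42 turned to 0.13 and Tie1 to 0.50 (log2 fold change) with the covariate, and Zfp42 to 0.14, Tie1 to 0.50 and Tep1 to -0.028 without KO 2 and KO 3. Of 80 called named genes, edgeR with TMM tested 77 and called 77 of them, the block kept 63, the fit without KO 2 and KO 3 kept 13 of 79 and the covariate 2. No called named gene reversed. The difference in genes with a read ranged from -256.7 to 125.0 over the leave-one-out sets. Equal replicate numbers did not pair the libraries: their deviations correlated at -0.120, 0.0256 and 0.0221, so not every library correlated best with its own number. A fit with the number as a replicate block, which also leaves out WT 4, gave 1010 genes and 5 lists. Leaving out WT 4 without a block gave 902 genes and the same 5 lists. The share of reads with mitochondrially encoded genes left out was not run, as the table holds no such genes, and DESeq2 gave no list test. Depth and the number of libraries limit small changes: in simulated counts 58.0% of genes changed by 1 log2 unit were called. Those genes were all above a minimum mean count, so the share does not hold for the lowest genes.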

Other observations

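The tests of how far the median of each gene class moved over splits, the tests on the Zfp genes of the trend with GC content and transcript length and of a chromosome 4 segment, the test and counts on granulosa cell RNA, the test of growth stage, and the fits with a granulosa covariate, without KO 2 and KO 3 and with that trend removed were chosen only after the result was seen. Camera on the gene classes was not among the tests fixed beforehand either.

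Genes named Zfp with a number, most of which encode zinc finger proteins, were higher in KO as a class. Of 361 tested, 56 rose and 0 fell by limma, with a median log2 fold change of 0.31 over the class, and 55 rose and 0 fell by edgeR. Camera with an estimated correlation gave p = 0.0101, which is not adjusted for the choice of this class after its shift was seen. In place of 56, limma called 27 higher without WT 1, 26 without WT 2, 31 without WT 3, 34 without WT 4, 27 without KO 2 and 19 without KO 3. Examples, chosen after their values were seen and not the genes with the smallest p throughout, were Zfp644 (165 ± 10.4 normalised counts in WT and 379 ± 54.7 in KO; adjusted p = 0.000415) and Zfp62 (202 ± 18.5 and 434 ± 122; adjusted p = 0.00118). The median of the class stayed above 0 under each scaling tried. Of 1852 long noncoding and antisense RNA genes tested, 137 fell and 10 rose, with a median of -0.25, but the class was not set apart by camera with an estimated correlation (p = 0.105). In place of 137, limma called 70 lower without WT 1, 79 without WT 2, 57 without WT 3, 89 without WT 4 and 58 without KO 2, and voom with quality weights called 89. Examples chosen in the same way were 0610033M10Rik (259 ± 46.0 and 50.2 ± 22.3; adjusted p = 0.000162) and Gm42980 (2164 ± 194 and 1097 ± 254; adjusted p = 0.000559). Mt1, a metallothionein gene chosen after its values were seen, had 162 ± 279 in WT and 2732 ± 574 in KO (log2 fold change 5.71, SE 1.37), higher in all 3 KO libraries than in all 4 WT libraries, but did not pass (limma adjusted p = 0.0821). WT 3 had 580.4 against 17.3 to 31.5 in the other WT libraries.

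Of the 35 splits of the 7 libraries into 4 and 3, 1, the real one, gave as many as 1291 called genes. The highest of the others gave 23. A share of 1 in 35 (0.0286) is the smallest these splits allow, so chance is argued against, but not excluded, for that count. Each of the other splits mixes KO and WT libraries in a group. A difference between KO and WT then widens the spread within that group, so the size of the gap does not measure chance. For the 7 called lists, 8 of the 35 splits gave as many and the highest of the others gave 11, so chance cannot be excluded for the number of called lists.

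For the Zfp genes, the median log2 fold change of the class less that of all tested genes was 0.321. Of the 35 splits 1, the real one, moved it as far from 0, and the highest of the others gave 0.262. That share (0.0286) is the smallest that 35 splits allow, so chance is argued against, but not excluded, for the split of the libraries. It is not argued against for the choice of this class, which was made after its shift was seen. Only 3.57% of the 56 (2 genes) lay within 10 Mb of Mfn2, so most of them do not lie in a chromosome 4 segment carried along with the Mfn2 allele. Whether such a segment acts on genes elsewhere was not tested. Among 232 Zfp genes with under 1% of their 75-base stretches shared with another gene, 13.8% were called higher, against 3.09% of all tested genes. The exact 95% interval over genes was 9.63 to 18.9. That share argues against reads shared between paralogs as the whole cause. After each library's trend with GC content and transcript length was removed, 69.8% of 53 were still called, between the bounds of 50% and 75% set first, and by a criterion added after that value was seen, 11.2% of the 340 Zfp genes with known length and GC content (exact 95% interval 8.03 to 15.0) were called higher after the removal, 38 genes with 37 of the 53 among them, against 3.32% of all tested genes, while 2 were called lower, which argues against the trend as the whole cause. The median log2 fold change of those 53 was 0.90 (SD 0.47) before and 0.84 (SD 0.47) after, and why some calls ended was not tested. An effect of genotype, a chromosome 4 segment acting on genes elsewhere and RNA of other cells stay open, as no test here decided between them. By limma 0 Zfp genes were called with the granulosa covariate (class median 0.34) or without KO 2 and KO 3 (0.29). The 56 had a median log2 fold change of 0.90 (SD 0.52, median SE 0.22), then 0.80 (SD 0.59, SE 0.35) with the covariate and 0.72 (SD 0.42, SE 0.31; 54 tested) without KO 2 and KO 3, so the calls ended with larger standard errors as well as lower folds and do not speak for either.

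For the noncoding genes, that difference of medians was 0.239 in size in the real split, and 2 of the 35 splits, the real one included, moved it as far. The highest of the others gave 0.241 (WT 1, WT 3 and WT 4 against the rest), so chance cannot be excluded for a shift of this class. Of 134 genes called lower, 82.8% were still called after the trend with GC content and transcript length was removed (median log2 fold change -1.20, SD 0.62, before and -1.12, SD 0.63, after), which argues against that trend as the whole cause. Over the 1813 with known length and GC content 118 were then called lower and 21 higher, and the share called lower was 6.51% (exact 95% interval 5.42 to 7.74) against 4.19% of all tested genes. Low expression level is argued against by protein-coding genes matched 1 to 1 on mean expression. Of their 97 calls 49.5% were lower (exact 95% interval 39.2 to 59.8), against 93.2% for the noncoding genes. The noncoding genes called lower lost a median of 49.6 normalised counts per kb of transcript. Over 293 olfactory receptor genes the mean loss was 0.38 (95% bootstrap interval -0.11 to 1.00). The former were picked for their fall and the receptor genes were not. The gap thus argues against genomic DNA in the WT libraries only for the genes called lower, and does not decide it for the class. Without strand, reads of overlapping genes cannot be separated, but 103 of the 137 overlap no protein-coding gene. An effect of genotype and RNA of other cells stay open, as no test here decided between them. With the granulosa covariate 1 gene was called lower (class median -0.25) and without KO 2 and KO 3 17 were (-0.21). The 137 had a median log2 fold change of -1.19 (SD 0.62, median SE 0.28), then -1.02 (SD 0.58, SE 0.44) and -0.95 (SD 0.57, SE 0.32), so these lost calls do not speak for either.

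Where the granulosa marker RNA of KO 2 and KO 3 came from stays open. The protocol has an enzyme digestion to remove granulosa cells, and 12 of the 28 markers in the table had a WT mean of at least 10. The most abundant was Serpine2, with a mean of 3088 in WT, 4275 in KO 2 and 3683 in KO 3. Its value in WT 4 (3740) lay above that in KO 3. Granulosa cell RNA as a source of the genes called higher, whole or in part, cannot be told apart from an effect of genotype. The 500 genes highest in KO 2 and KO 3 against WT 3 and WT 4 had a median log2 difference of 0.43 between KO 1 and WT 1 and WT 2 (95% bootstrap interval over genes 0.38 to 0.47), but 1 KO library has no spread between libraries. Of the 594 genes called higher, 94.4% were above every WT library in KO 1. KO 1 was part of the fit that called them, so this share followed largely from the selection and does not bear on the source. Of 11 germ cell genes called higher, 5 gained more normalised counts in KO 2 and KO 3 than the marker that gained most (891). The other 6 gained less. That marker was Serpine2, which was also abundant in WT. The difference over the 500 genes and the gains of the 5 germ cell genes go against granulosa RNA as the whole source. They come from 1 KO library or from genes picked because they were higher, so they do not exclude it. By limma 98 genes (1 higher) were called without KO 2 and KO 3 and 11 (0 higher; 1635 at an unadjusted p under 0.05) with the covariate, but both settings also leave less to tell the groups apart, so these counts do not decide. For the higher germ cell genes, an earlier stage of growth of KO oocytes cannot be told apart from an effect of genotype, because the zona list had a median log2 fold change of -0.031 (95% bootstrap interval -0.13 to 0.14) and the maternal effect list 0.03 (-0.09 to 0.20), with members in both directions.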
